A study of Anopheles coluzzii and Anopheles merus with 32 samples.

How the data were processed

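Whole larvae of An. coluzzii and An. merus were sequenced as 32 libraries, each from a pool of 35 to 50 larvae, in 8 groups of 4 formed by 2 species, 2 ages (18 h and 66 h after hatching) and 2 waters (FW or SW for 6 h). Per the labels' protocols, total RNA was treated with DNase and libraries were made with the Illumina TruSeq RNA v2 kit with a polyA selection step. That kit does not mark strand, so reads from overlapping genes on opposite strands cannot be told apart. Groups were read from the sample titles and characteristics. Nothing in the labels says that the pools of a group came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

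The deposited table is a gene-level signal, named by the authors as CPM (read counts relative to library size) scaled by the trimmed mean of M values (TMM), for 11025 gene identifiers. The tests had been planned for CPM, and the same test was used for this signal. Per the submitters' processing notes, Trimmomatic, Bowtie2, TopHat2, HTSeq and edgeR were used, named without role or version, and the table is named as filtered, by a rule that is not given in the sources used here. The genome build and annotation are likewise not given. Both species share 1 set of identifiers. A gene whose reads align less readily in 1 species carries that difference in each of its groups, which acts on the differences between species and largely cancels in the comparisons of SW with FW. All 32 columns were used. The column sums, 737787 to 1481287, differ between libraries as TMM factors make them.

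In each library the values were whole multiples of the value of 1 read. Dividing by it gave whole reads for 100% of the values within a tolerance of 0.01 reads. TMM factors recomputed from these reads with edgeR 4.0.16 differed from the authors' by at most 6.7e-16. Group means of the factor ran from 0.692 in An. merus at 66 h in SW to 1.31 in An. coluzzii at 18 h in FW. Read totals were 3769859 to 16633623. The 48 pairs of replicates of a group differed by 5.36 to 50.3 times the sampling noise (chi-square per degree of freedom over genes with at least 20 reads in the pair). No pair was therefore taken as the same library read again. These values do not show that the libraries of a group are independent. Reads carry no molecular identifiers, so statements on few or no reads cover counting error only.

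The comparisons and their tests were fixed before the data were examined. Because the deposited unit is not a count, values were tested as log2(CPM + 1) in R 4.3.3 with limma 3.58.1. A single linear model with 8 group means was fitted to all 32 libraries (24 residual degrees of freedom), with empirical Bayes moderation using the trend and robust options. Tests were two-sided with Benjamini-Hochberg adjustment within each of 12 comparisons, and genes with an adjusted p below 0.05 are called. Genes with a mean of at least 1 CPM over all libraries were tested, which kept 10505 and left out 520. Fold changes are on the log2(CPM + 1) scale, which understates changes of genes with low values. The 12 comparisons were SW against FW in each species and age, the interactions of species with water and of age with water, the species difference in FW at each age and the age difference in FW in each species. Agreement between comparisons was described by correlations across genes, with a jackknife over libraries, and by Fisher's exact test of shared calls. Figures were drawn with matplotlib 3.10.9.

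Of the 11025 identifiers, 0 were found in the gene name table available here, and the files do not pair identifiers with names. The 26 gene lists fixed in advance, for ion transport, stress response, cuticle and tissue markers among others, therefore matched no gene and no list was tested. For the same reason genes are given by identifier. The rule for naming genes took, per comparison, the 2 highest and 2 lowest log2 fold changes among called genes with a mean of at least 5 CPM in the highest group and, for comparisons of 2 groups, no overlap between the libraries. AGAP002360 under SW and the runs of neighbouring identifiers in the closing observations were chosen after their values were seen. Reads shared between near-identical gene copies could not be examined.

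The model was tested on simulated counts drawn from the real means and library sizes, with 200 of 10505 genes changed. The changed genes were taken from those with a mean of at least 5 CPM in the compared groups, so recovery below that was not examined. For SW against FW in An. coluzzii at 18 h it recovered 25.4%, 79.1% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold, and 37.3%, 86.6% and 98.5% at 66 h. In An. merus the shares were 61.2%, 94% and 100% at 18 h, and 46.3%, 95.5% and 98.5% at 66 h. False calls made up 7.5%, 9.8%, 6.6% and 5.3% of the calls in these comparisons, in the same order. Genes were drawn independently, and the dispersion of the compared libraries was given to all libraries. Unequal spread between groups and differences between pairs of replicates were therefore not simulated. Nor was a change as wide as the 51.7% and 57.2% of genes called in An. merus at 18 h and 66 h. The shares do not cover what these do to the real calls, such as those in An. coluzzii at 18 h.

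Alternatives fixed in advance were pseudocounts of 0.25 and 4, a minimum mean of 5 CPM or none, the same column sum for every library, quantile normalisation, a fit over only the libraries of a comparison, moderation without trend and robust options, and each replicate left out in turn. Alternatives chosen after seeing the data were the edgeR quasi-likelihood test on the recovered reads, reads of every library thinned to 3769859, An. coluzzii 18 h FW replicates 1 and 2 left out together, and a fit to the 16 means of replicates 1 and 2 and of replicates 3 and 4 (8 residual degrees of freedom). The edgeR test called 766 and 222 genes under SW in An. coluzzii at 18 h and 66 h, and 5580 and 6078 in An. merus.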

Results

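Messenger RNA was measured in whole larvae of 2 sibling malaria mosquitoes, Anopheles coluzzii and Anopheles merus, which the series title sets against each other as stenohaline and euryhaline, that is, tolerant of a narrow or a wide range of salinity. All larvae were reared in freshwater (FW). At 18 h or 66 h after hatching, pools of 35 to 50 larvae were placed for 6 h in either FW or saltwater (SW), and 1 library was made from each pool. The labels do not state the salinity of the SW, nor whether both species received the same water. Each of the 8 combinations of species, age and water was represented by 4 libraries, 32 in all. Read totals recovered from the table ran from 3769859 to 16633623 per library. The shallowest group was An. coluzzii at 18 h in SW, with 3769859 to 7588059 reads, and An. merus at 66 h in FW was among the deepest, with 11031968 to 16621515.

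Age and species separated the libraries more than water did. The first principal component, with 40.8% of the variance, parted the 18 h libraries from the 66 h libraries in both species. The second, with 31%, parted the species, and it also placed the SW libraries of An. merus above its FW libraries, at 45.9 ± 1.7 against 13 ± 4.8 at 18 h and at 65 ± 3.1 against 29.1 ± 3.3 at 66 h (mean ± SD of the component, n = 4). In An. coluzzii the SW libraries also lay above the FW libraries at 18 h, at -34.9 ± 4.6 against -50 ± 7.2, while at 66 h, at -31.4 ± 3.1 against -36.6 ± 3.8, the libraries overlapped. The third, with 9.36%, parted FW from SW in An. merus, at -36.3 ± 1.6 and 18.5 ± 5.6 at 18 h, and also parted the species in FW. The FW and SW libraries of An. coluzzii stood at 1.66 ± 3.6 and 15.3 ± 9 at 18 h, where they overlapped, and at -1.9 ± 3.2 and 13.3 ± 2.7 at 66 h, where they did not.

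**Figure D1:**
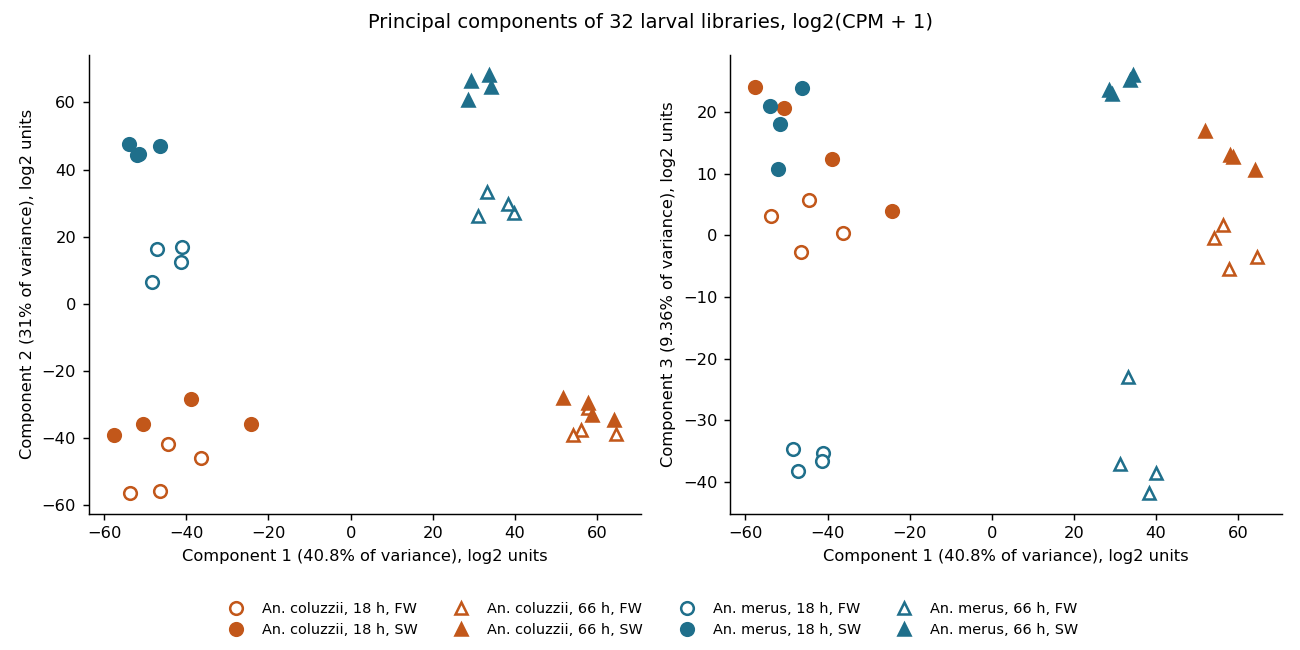
Principal components of the 32 libraries on log2(CPM + 1) values, with component 1 on both x axes and components 2 and 3 on the y axes; each point is 1 library, filled for SW and open for FW, round for 18 h and triangular for 66 h. The SW libraries of An. merus lie apart from its FW libraries on component 3, which carries 9.36% of the variance.

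The design tests the impact of salinity on mRNA levels. In An. merus at 18 h, 6 h of SW changed 5430 of 10505 genes, of which 2643 rose and 2787 fell (limma, adjusted p below 0.05). The change was at least 2-fold for 1173 of them, and for 730 with a pseudocount of 4. AGAP009460 rose from 1.16 ± 0.107 to 117 ± 15.5 CPM (mean ± SD, n = 4), a log2 fold change of 5.76 ± 0.19 (SE, adjusted p = 6.4e-20). AGAP004581 rose from 1.55 ± 0.688 to 62.7 ± 10.5 CPM, a log2 fold change of 4.67 ± 0.3. AGAP002331 fell from 46.1 ± 8.3 to 3.8 ± 0.938 CPM, a log2 fold change of -3.3 ± 0.2 (adjusted p = 1.2e-13), and AGAP013737 fell from 14.2 ± 5.87 to 0.92 ± 0.374 CPM. The naming rule required that all 4 SW libraries of each of these genes lie on the same side of all 4 FW libraries. The share of called genes that rose was 48.7%, and 29.5% when every library was rescaled to the same sum, a scaling under which the median of all genes moved from -0.02 to -0.21 on the log2 scale, so directions here are relative to the bulk of genes as the authors' scaling sets it.

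At 66 h SW changed 6014 genes in An. merus, with 2714 higher and 3300 lower, and 1473 of them changed at least 2-fold (868 with a pseudocount of 4). AGAP004581 again stood among the highest, at 0.816 ± 0.429 CPM in FW and 115 ± 28.8 CPM in SW (log2 fold change 5.98 ± 0.3, adjusted p = 2.1e-15). AGAP004583 rose from 0.559 ± 0.21 to 74.7 ± 15.7 CPM, a log2 fold change of 5.59 ± 0.22. AGAP009460, the leading gene at 18 h, rose at 66 h too, with group means of 2.18 and 120 CPM. AGAP003269 fell from 120 ± 21.4 to 16.1 ± 3.75 CPM (log2 fold change -2.83 ± 0.19, adjusted p = 4.5e-13), and AGAP013318 fell from 356 ± 123 to 48.2 ± 10.4 CPM (log2 fold change -2.82 ± 0.39). The share of called genes that rose was 45.1%, and 27.2% with every library scaled to the same sum, where the median of all genes moved from -0.06 to -0.27.

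**Figure D2:**
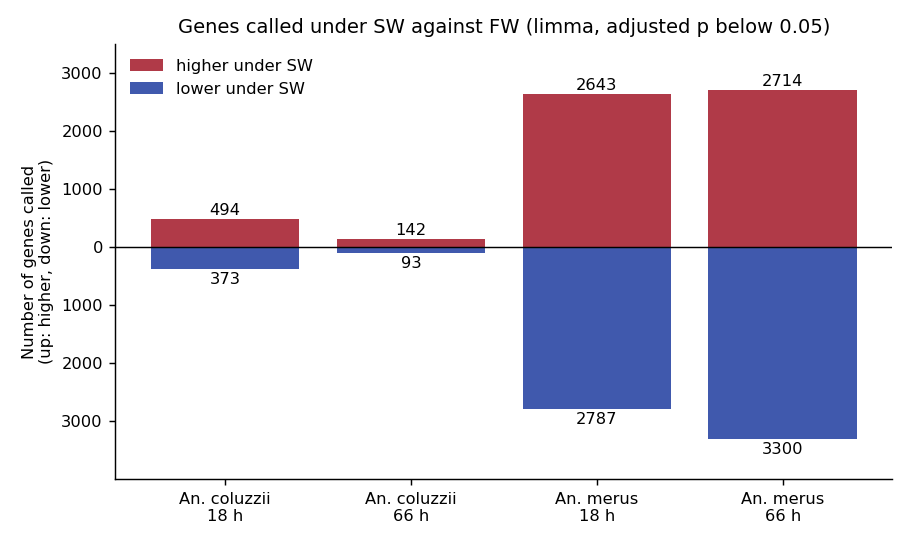
Number of genes called under SW against FW in each species and age (limma, adjusted p below 0.05, 10505 genes tested, 4 libraries per group), with genes higher under SW drawn upward and genes lower drawn downward. The 2 An. merus bars hold 5430 and 6014 genes and the 2 An. coluzzii bars 867 and 235.

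In An. coluzzii at 66 h, SW changed 235 genes, with 142 higher and 93 lower. AGAP028216 rose from 1.45 ± 1.12 to 10.1 ± 2.35 CPM, a log2 fold change of 2.25 ± 0.19 (SE, adjusted p = 2.1e-08). AGAP001610 rose from 2.71 ± 0.891 to 13.9 ± 3.75 CPM. AGAP003269 fell from 55.2 ± 15.2 to 16.5 ± 2.63 CPM (log2 fold change -1.65 ± 0.19, adjusted p = 1.8e-06), and it also fell in An. merus at this age. AGAP011426 fell from 16.4 ± 1.46 to 5.75 ± 1.02 CPM. In a fit over the 8 libraries of this comparison alone, 161 genes were called, 75 higher and 86 lower, and they held 46.4% of the 235. With the means of replicates 1 and 2 and of replicates 3 and 4 as the units, 52 were called, 36 higher and 16 lower. The number of calls was 129 with every library thinned to 3769859 reads. It was 132 without FW replicate 2, and 146, 110 and 118 without SW replicates 1, 2 and 3.

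In An. coluzzii at 18 h, 867 genes were called under SW, with 494 higher and 373 lower, but this number rested on few libraries and on the spread pooled over all 8 groups. AGAP010863 stood at 7.4 ± 2.81 CPM in FW and 23.9 ± 6.1 CPM in SW, a log2 fold change of 1.6 ± 0.18 (adjusted p = 1.1e-05). AGAP003350 stood at 201 ± 39.6 CPM in FW and 639 ± 300 CPM in SW. Its SW values fell over replicates 1 to 4, at 1043, 687, 447 and 379 CPM. It also differed with age, at 2094 to 2958 CPM in FW at 66 h, so its difference here may not be due to water alone. AGAP007830 was lower under SW, at 16.3 ± 5.82 against 50.6 ± 8.8 CPM (log2 fold change -1.65 ± 0.26, adjusted p = 0.00064), and AGAP009916 was lower at 8.02 ± 4.04 against 25 ± 3.74 CPM. In a fit over the 8 libraries of this comparison alone, only 6 genes were called with 1745 at an unadjusted p below 0.05, and none of these 4 genes was among them, with adjusted p from 0.0777 to 0.131. With the means of replicates 1 and 2 and of 3 and 4 as the units 10 genes were called, and AGAP003350 (adjusted p = 0.147), AGAP007830 (0.0524) and AGAP009916 (0.131) were not. FW replicates 1 and 2 lay apart from replicates 3 and 4, and without both of them 18 genes were called, with adjusted p of 0.246 for AGAP003350 and 0.125 for AGAP009916. The count was 174, 135 and 1729 without FW replicates 1, 2 and 4, and 1503, 459 and 362 without SW replicates 1, 2 and 3. With every library thinned to 3769859 reads it was 439. The share that was higher was 57%, and 39.5% with every library scaled to the same sum.

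**Figure D3:**
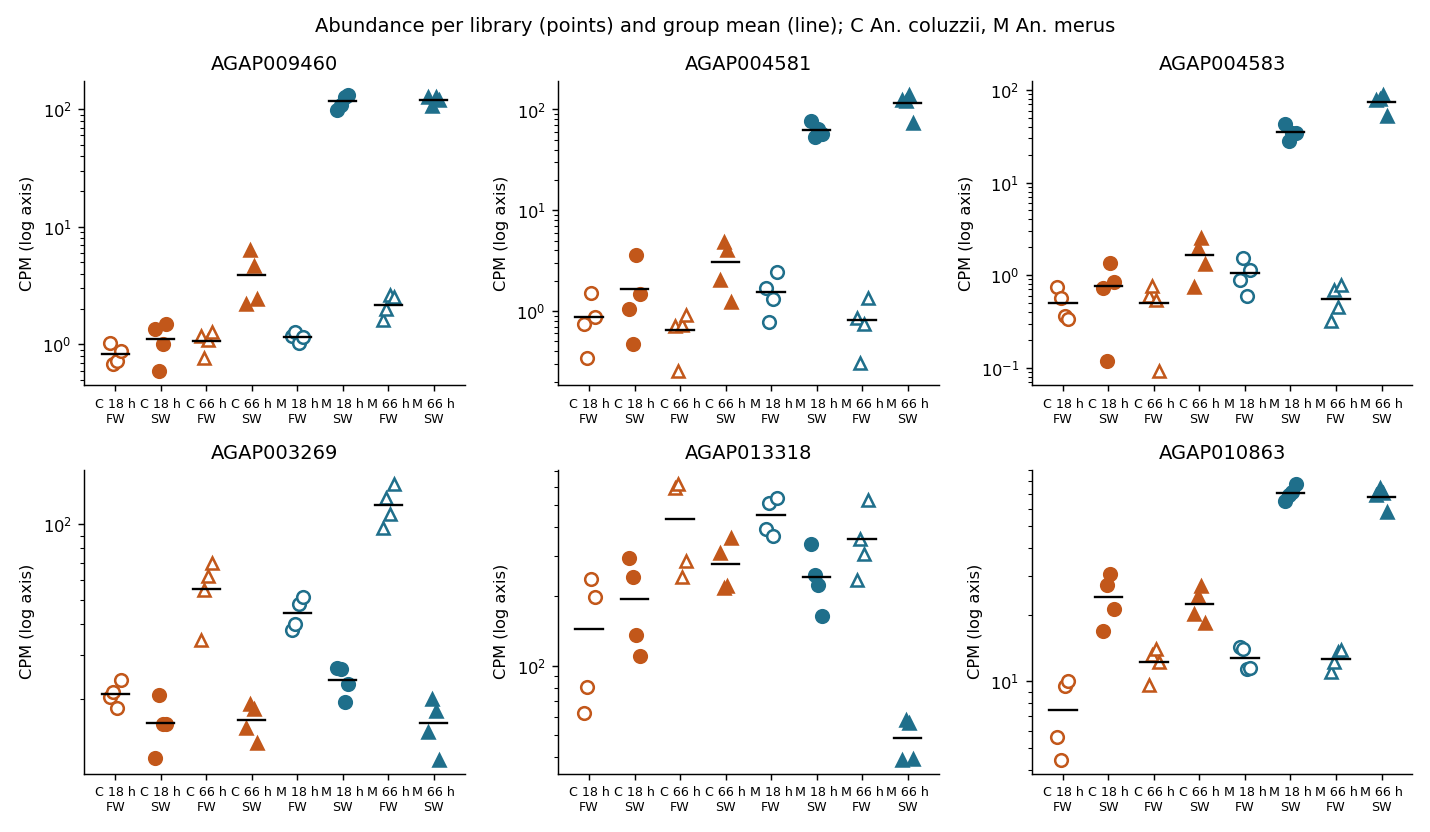
Abundance of 6 genes in every library, in CPM on a log axis, with groups on the x axis (C for An. coluzzii, M for An. merus); points are libraries, filled for SW, and black lines are group means of 4 libraries. AGAP009460, AGAP004581 and AGAP004583 stand near or above 34.9 CPM on average in the SW groups of An. merus and at 3.92 CPM or less on average in every other group.

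Whether the response to SW differed between the species was tested directly by the interaction of species and water. At 18 h it was called for 2201 genes, 1151 with the more positive change in An. merus and 1050 with the more negative. The absolute change was larger in An. merus for 2091 of them, or 95%. AGAP009460 led, with an interaction of 5.57 ± 0.26 (log2, SE, adjusted p = 2.7e-15). In An. coluzzii it stood at 0.827 ± 0.16 CPM in FW and 1.11 ± 0.403 CPM in SW, against 1.16 and 117 CPM in An. merus. AGAP004581 followed at 4.26 ± 0.42. The most negative interactions were those of AGAP002849, at -3.14 ± 0.87 (adjusted p = 0.011), and AGAP001722, at -3.02 ± 0.93 (adjusted p = 0.022), and both were highly variable between libraries. AGAP001722 stood at 115 ± 110 and 384 ± 297 CPM in FW and SW in An. coluzzii and at 131 ± 73.8 and 65.9 ± 20.5 CPM in An. merus. Its adjusted p was 0.0536 and 0.0507 without An. coluzzii FW replicates 1 and 2, 0.0551 without An. coluzzii SW replicate 1 and 0.0511 without An. merus FW replicate 3. AGAP002849 moved to -2.52, -3.74 and -3.77 without An. coluzzii FW replicate 1, FW replicate 3 and SW replicate 4, and AGAP001722 to -2.25 without FW replicate 1. In a fit over the 16 libraries of the comparison, neither AGAP002849 (adjusted p = 0.0752) nor AGAP001722 (0.125) passed, nor did they without both An. coluzzii FW replicates 1 and 2 (0.118 and 0.207). With the means of replicates 1 and 2 and of 3 and 4 as the units, 935 genes were called, without AGAP002849 (0.151) and AGAP001722 (0.208). The positive share was 52.3%, and 28.9% with every library scaled to the same sum.

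At 66 h the interaction of species and water was called for 3368 genes, 1527 positive and 1841 negative, and the absolute change was larger in An. merus for 3271 of them, or 97.1%. AGAP004583 had an interaction of 4.79 ± 0.31 (adjusted p = 7e-12) and AGAP004581 of 4.78 ± 0.42 (adjusted p = 2.3e-09). Both genes were low in An. coluzzii at this age. AGAP004581 stood there at 0.649 ± 0.281 CPM in FW and 3.06 ± 1.71 CPM in SW, and AGAP004583 at 0.495 ± 0.285 and 1.64 ± 0.78 CPM. AGAP005997 had an interaction of -2.65 ± 0.22 (adjusted p = 1.1e-09). It fell from 1460 ± 232 to 217 ± 31 CPM in An. merus, while in An. coluzzii it stood at 834 ± 163 CPM in FW and 783 ± 116 CPM in SW. AGAP010123, at -2.5 ± 0.93 (adjusted p = 0.041), lost its call in a fit over the 16 libraries of the comparison (adjusted p = 0.166). It also lost it, with adjusted p from 0.0547 to 0.0907, without An. coluzzii FW replicate 2 or SW replicates 1, 2 or 4, and without An. merus FW replicates 1, 3 or 4 or SW replicates 1 or 4. Without An. coluzzii FW replicates 1 and 2 in turn its interaction was -3.23 and -1.5. On the means of replicates 1 and 2 and of 3 and 4, 2102 genes were called. The positive share of calls was 45.3%, and 21.4% with every library scaled to the same sum.

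The species moved many of the same genes in the same direction. Of the 867 genes called in An. coluzzii at 18 h, 808 (93.2%) had the same sign of change in An. merus. Of them 391 were called higher in both species and 309 lower in both, where lists drawn independently would share 124 and 99 (Fisher's exact test, odds ratios 13.1 and 14.9, p = 7.2e-148 and 3e-119), and 22 were called in opposite directions. At 66 h, 113 genes were higher in both and 64 lower in both, against 36.7 and 29.2 for independent lists (Fisher's exact test, odds ratios 11.6 and 4.89, p = 2.3e-41 and 1.4e-13). Fisher's test treats genes as independent units, so its p-values do not measure the spread between libraries. The pooled fit also gives a gene the same spread in both species, which can raise the overlap above that of independent lists. Across all genes, which are not independent replicates, the log2 fold changes of the species had a Pearson r of 0.542 and a Spearman rho of 0.578 at 18 h, and 0.463 and 0.499 at 66 h. The jackknife standard errors over the libraries were 0.12 and 0.091. These 4 comparisons share no library. The overlap at 18 h carries the limits of the An. coluzzii calls, and with each comparison fitted on its own libraries 2 genes were higher and 3 lower in both species. At 66 h that fit left 53 higher and 62 lower. With the means of replicates 1 and 2 and of 3 and 4 as the units, 4 were higher and 5 lower at 18 h, and 25 and 9 at 66 h.

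**Figure D4:**
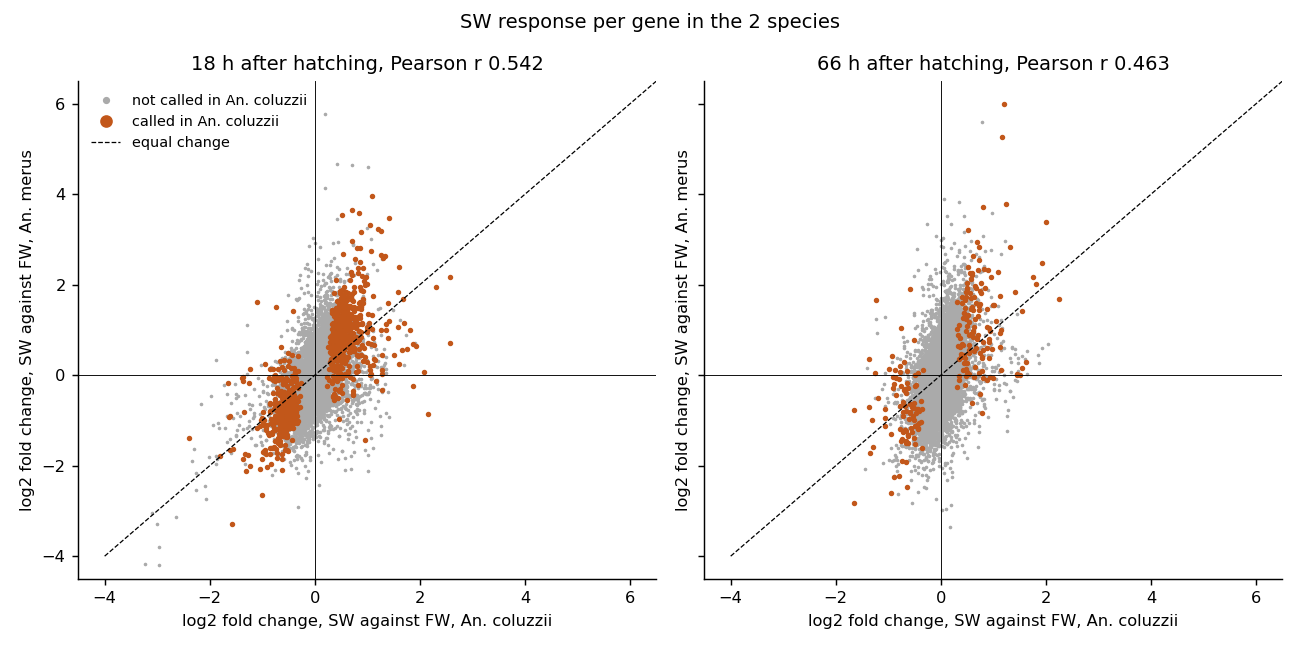
Log2 fold change under SW of each of 10505 genes in An. coluzzii (x axis) and An. merus (y axis) at both ages, with genes called in An. coluzzii in orange and the line of equal change dashed. Pearson r was 0.542 at 18 h and 0.463 at 66 h, and the cloud is steeper than the line of equal change.

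Genes called in the same direction in all 4 SW comparisons numbered 38 higher and 26 lower, where independent lists would give 0.43 and 0.28. AGAP010863 was among those that rose, at log2 fold changes of 1.6 and 0.82 in An. coluzzii and 2.39 and 2.34 in An. merus, at 18 h and 66 h. AGAP002331 was among those that fell, at -1.57 and -0.88 in An. coluzzii and -3.3 and -2.25 in An. merus. Since 6 genes were called in An. coluzzii at 18 h on its own libraries and 10 on means of replicates, these numbers rest on the pooled spread. In total 7499 genes were called in at least 1 of the 4 comparisons, and 171 of them were called higher in 1 comparison and lower in another.

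Whether the response depended on larval age was tested by the interaction of age and water. In An. merus it was called for 1393 genes, 574 with the more positive change at 66 h and 819 with the more negative. Of these, 421 were called at both ages in the same direction, 108 at both ages in opposite directions, 517 at 66 h alone and 339 at 18 h alone. AGAP004501 rose at 18 h, from 23.4 ± 7.09 to 109 ± 10.2 CPM, and fell at 66 h, from 401 ± 84.3 to 115 ± 12 CPM (interaction -3.98 ± 0.47, adjusted p = 4.2e-06). AGAP009591 went from 147 ± 18.1 CPM in FW to 43.1 ± 5.45 CPM in SW at 18 h, and from 24.9 ± 15.3 to 54.2 ± 9.55 CPM at 66 h (interaction 3.04 ± 0.59, adjusted p = 0.0013). AGAP000239 had an interaction of -3.77 ± 0.61, with 1.19 ± 0.338 and 53.5 ± 14.4 CPM at 18 h and 156 ± 96.9 and 231 ± 38 CPM at 66 h. AGAP010811 had an interaction of 2.91 ± 0.55, with few reads at 18 h (35 over the FW libraries and 14 over the SW libraries). It stood at 1.05 ± 0.56 and 0.23 ± 0.237 CPM at 18 h and at 4.06 ± 1.72 and 21.2 ± 4.03 CPM at 66 h. Over the alternatives its interaction ran from 1.91 to 4.24, so its size is uncertain. On the means of replicates 1 and 2 and of 3 and 4, 393 genes were called, and these 4 were among them. Across genes the responses at the 2 ages of An. merus had a Pearson r of 0.752, with a jackknife standard error of 0.039, and 1879 genes were higher and 2069 lower at both ages, against 683 and 875 for independent lists.

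In An. coluzzii the interaction of age and water was called for 8 genes, 5 positive and 3 negative, with 977 at an unadjusted p below 0.05. AGAP028216 was almost without reads at 18 h, with 1 read over the 4 FW libraries and 3 over the 4 SW libraries, and stood at 1.45 and 10.1 CPM at 66 h. Its interaction of 2.17 ± 0.28 (adjusted p = 0.00011) therefore depends on the pseudocount, and edgeR on the recovered reads gave an adjusted p of 0.973. AGAP004935 changed at 66 h, from 8.28 ± 1.84 to 27.9 ± 7.53 CPM, and stood at 7.09 ± 1.33 and 7.32 ± 1.56 CPM at 18 h (interaction 1.6 ± 0.24, adjusted p = 0.001, but 0.104 in a fit over the 16 libraries concerned and 0.0518 with thinned reads). AGAP011426 had an interaction of -1.41 ± 0.22 (adjusted p = 0.0013) and AGAP005795 of -1.59 ± 0.32 (adjusted p = 0.038). AGAP005795 lost its call, with adjusted p from 0.0524 to 0.158, without 18 h FW replicates 1, 2 or 3, 18 h SW replicate 2, 66 h FW replicates 2, 3 or 4 or 66 h SW replicates 1, 2 or 3. With the means of replicates 1 and 2 and of 3 and 4 as the units 3 genes were called, and AGAP028216 (adjusted p = 0.0623), AGAP005795 (0.154) and AGAP011426 (0.135) were not. The number of called genes was 16 without 18 h FW replicate 4, 27 without 18 h SW replicate 1 or 4, and 5 without 18 h FW replicate 1 or 2, 66 h FW replicate 3 or 66 h SW replicate 1. The positive share of the calls was 62.5%, and 45.5% after quantile normalisation. Across genes the responses at the 2 ages had a Pearson r of 0.251 with a jackknife standard error of 0.23. With 1 library left out it ran from 0.156 (without 18 h SW replicate 4) to 0.365 (without 66 h FW replicate 2). Noise between libraries lowers such an r. With it taken off, the SD of log2 fold changes in An. coluzzii was 0.266 at 18 h and 0.198 at 66 h, against 0.371 and 0.286 observed. In An. merus these were 0.655 and 0.701 against 0.676 and 0.731, so the r values of the species are not directly comparable. At both ages 45 genes of An. coluzzii were higher and 38 lower (2 and 3 with each comparison fitted on its own libraries, and 1 and 1 on the means of replicates).

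The species also differed in FW. At 18 h, 4915 genes differed, 2554 higher in An. merus and 2361 lower. At 66 h, 5360 differed, 2842 higher and 2518 lower. AGAP010613 stood at 71.5 ± 11.7 CPM in An. merus and 0.508 ± 0.369 CPM in An. coluzzii at 18 h (log2 difference 5.6 ± 0.21, adjusted p = 5.6e-19). AGAP005457 stood at 399 ± 232 CPM in An. merus and 6.8 ± 7.23 CPM in An. coluzzii, and its log2 difference of 5.64 ± 0.72 was 6.47 without An. merus FW replicate 3. AGAP007187 was lower in An. merus, at 2.91 ± 0.551 against 595 ± 92.7 CPM (log2 difference -7.25 ± 0.4), as was AGAP010816, at 2.47 ± 0.774 against 169 ± 16.5 CPM. At 66 h the most positive differences were those of AGAP002360, at 190 ± 58.4 CPM in An. merus and 0.175 ± 0.159 CPM in An. coluzzii, and AGAP005690, at 146 ± 113 and 0.739 ± 0.777 CPM. In the other direction stood AGAP007227, at 0.154 ± 0.0481 against 245 ± 76 CPM, and AGAP007229, at 0.264 ± 0.148 against 168 ± 21.7 CPM. Among calls of at least 2-fold, 573 were higher and 715 lower in An. merus at 18 h, and 385 and 954 at 66 h. The higher share of all calls in An. merus was 52% at 18 h and 53% at 66 h, and 35.4% and 31.6% with every library scaled to the same sum. The median of all genes then moved from 0.03 to -0.1 and from 0.06 to -0.12. Across genes the differences at the 2 ages had a Pearson r of 0.744. Among genes with at least 5 CPM in An. coluzzii, 11 at 18 h and 18 at 66 h had at most 3 reads over the 4 An. merus libraries. In the other direction there were 3 and 4. Sequence differences from the reference used for counting, which is not given in the sources used here, act on these values in full.

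AGAP002360 also rose under SW in An. merus, from group means of 53.1 to 240.8 CPM at 18 h and from 190 to 724 CPM at 66 h (log2 fold changes 2.27 and 1.96, adjusted p = 3.73e-07 and 2.6e-06). In An. coluzzii it stood at 1.42 CPM in FW and 2.14 CPM in SW at 18 h, and its SW calls did not pass at either age (adjusted p = 0.549 and 0.418). The interaction of species and water for AGAP002360 was 1.97 ± 0.42 at 18 h (adjusted p = 0.00122) and 1.46 ± 0.42 at 66 h (adjusted p = 0.00813).

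The ages were compared in FW. In An. coluzzii 6154 genes were called between 18 h and 66 h, 3137 higher at 66 h and 3017 lower. In An. merus 5339 were called, 2830 higher and 2509 lower. In An. coluzzii AGAP013147 rose from 1.87 ± 0.499 to 906 ± 146 CPM (log2 fold change 8.31 ± 0.23, adjusted p = 2.5e-21) and AGAP013729 from 0.24 ± 0.251 to 219 ± 66.4 CPM. AGAP011902 fell from 31.7 ± 7.33 to 3.17 ± 0.815 CPM and AGAP009878 from 32.1 ± 7.41 to 3.93 ± 2.61 CPM. In An. merus AGAP005951 rose from 3.81 ± 0.347 to 1530 ± 645 CPM (log2 fold change 8.23 ± 0.28, adjusted p = 2.2e-18) and AGAP013175 from 0.903 ± 0.341 to 338 ± 125 CPM. AGAP007990 fell from 78.2 ± 59.8 to 0.412 ± 0.392 CPM, a log2 fold change of -5.16 ± 0.67, and AGAP005458 fell from 197 ± 118 to 4.26 ± 1.71 CPM, a log2 fold change of -4.78 ± 0.77. Without FW replicate 3 at 18 h, these 2 values were -6.15 and -5.67. Across genes the age differences of the 2 species had a Pearson r of 0.844, and 2247 genes were higher and 2127 lower at 66 h in both, against 845 and 721 for independent lists. The higher share was 51% in An. coluzzii and 53% in An. merus. With every library scaled to the same sum it was 21.6% and 15.1%, and the median of all genes moved to -0.45 and -0.46. After quantile normalisation it was 40.6% and 43.8%, with medians of -0.11 and -0.05.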

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

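The tests of the spread between replicates, of thinned reads, of permuted residuals and of pairs of replicates as units were chosen after the results they bear on were seen. A difference between the species in the response to SW was called for 2201 genes at 18 h and 3368 at 66 h (limma interactions, adjusted p below 0.05). A difference between the ages was called for 1393 genes in An. merus and 8 in An. coluzzii, and chance was not excluded for these 8. The naming rule takes the 2 highest and 2 lowest values among called genes with a mean of at least 5 CPM in the highest group. Under it, the interactions of species and water at 18 h were those of AGAP009460 (log2 5.57), AGAP004581 (4.26), AGAP002849 (-3.14) and AGAP001722 (-3.02). At 66 h they were those of AGAP004583 (4.79), AGAP004581 (4.78), AGAP005997 (-2.65) and AGAP010123 (-2.5). Between the ages of An. merus they were those of AGAP009591 (3.04), AGAP010811 (2.91), AGAP004501 (-3.98) and AGAP000239 (-3.77), and between the ages of An. coluzzii those of AGAP028216 (2.17), AGAP004935 (1.6), AGAP005795 (-1.59) and AGAP011426 (-1.41). The lowest called value between the ages of An. coluzzii was -2.7, in a gene that the limit of 5 CPM left out.

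More genes were called under SW in An. merus than in An. coluzzii, by a factor of 6.26 at 18 h and 25.6 at 66 h, but of 996 at 18 h and 36.6 at 66 h in fits over the libraries of each comparison, and the 867 calls of An. coluzzii at 18 h became 135 without FW replicate 2 and 1729 without FW replicate 4. Deeper libraries are argued against, since the factors were 10.5 and 41 with every library thinned to 3769859 reads, and so is scaling, since the lower factor under other scalings was 4.19 at 18 h and 23.1 at 66 h. For development, only a shift along the difference between 18 h and 66 h could be examined. The An. merus response had a squared correlation across genes with the An. coluzzii age difference of 3.4e-05 ± 0.0013 (jackknife SE) at 18 h. At 66 h it was 0.00219 ± 0.0033. These values argue against such a shift as the main source of the response. A shift of a few hours or of another kind could not be examined with 2 ages. A smaller spread in An. merus is argued against: with both species judged by the spread of An. coluzzii alone, the lower of 2 factors was 22.2 at 18 h (5003 against 225 calls) and 37.2 at 66 h (5987 against 161); the noise-corrected SD of log2 fold changes in An. coluzzii was 0.406 ± 0.27 and 0.282 ± 0.064 of that in An. merus (jackknife SE). A biological difference between the species may underlie the pattern, but the labels do not say that both received the same SW, and that was not tested.

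FW replicates 1 and 2 of An. coluzzii at 18 h lay apart from replicates 3 and 4. Among 2805 genes of at least 50 CPM, where few reads add little noise, the SD of the difference between these pairs was 0.584, which is 2.51 times the median of 21 splits in the other groups, and this argues against low depth. The highest of these, 0.536, was the same split of the SW group at that age. On the first principal component, which parted the ages, SW replicates 1 to 4 of that group stood at -24.2, -38.8, -50.5 and -57.7. Their SD was 15, against 7.1 or less in the other groups. Whether these SW pools differed in development was not tested. For the FW pairs, the correlation across genes of their difference with the age difference of An. merus in FW was 0.229 ± 0.071 (jackknife SE). Pools at different points of development may therefore contribute, but neither this nor separate cultures could be settled. The pattern bears on the 867 genes called there, since 2 of the 35 splits of the 8 libraries gave as many, and a split that exchanged FW replicate 4 with SW replicate 1 gave 2150. Chance was therefore not excluded for that number, and the second split points to a structure of the samples other than water.

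The TMM factor of An. merus was lower under SW, by a log2 difference of -0.222 at 18 h and -0.25 at 66 h (two-sided exact permutation test, p = 0.029 each, the smallest that 4 against 4 libraries allow). In An. coluzzii it was -0.0526 (p = 0.11) and 0.000554 (p = 0.94) by the same exact test. The 100 most abundant genes are argued against as the whole cause at 18 h, where 0.868 ± 0.065 of the difference was left without them, while at 66 h 0.627 ± 0.029 was left and their part stays open. The 1051 genes of highest mean CPM had a median log2 fold change of 0.213 at 18 h and 0.247 at 66 h, which describes where the higher sum lies and not its cause. No biological explanation was tested.

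Splits of the libraries into other groups of the same sizes were refitted. For SW against FW, 1 of 35 splits, the real one, gave as many calls in An. coluzzii at 66 h (235, highest other 7), An. merus at 18 h (5430, highest other 1464) and An. merus at 66 h (6014, highest other 1593). The real split was likewise the only 1 of 35 with as many calls for the species difference at 18 h (4915, highest other 1014) and 66 h (5360, highest other 586). The same held for the age difference in An. coluzzii (6154, highest other 1779) and An. merus (5339, highest other 663). For the interactions, exchanging labels left as many calls in 6 of 100 splits for species and water at 18 h (2201, highest other 4303) and 6 at 66 h (3368, highest other 4800). For age and water it did so in 6 splits in An. merus (1393, highest other 3438) and 12 in An. coluzzii (8, highest other 1784). The exchange leaves the real water effects in the libraries. A split that mixes the waters on 1 side only can then call them as an interaction, so this exchange cannot decide on chance. With the species, age and water effects kept and the residuals permuted 100 times, the real one included, as many calls came in 1 draw for species and water at 18 h (highest other 665), 1 at 66 h (highest other 1304), 2 for age and water in An. merus (highest other 1621) and 5 in An. coluzzii (highest other 1492). The share of draws with as many calls was thus below 0.05 for the first 3, though in An. merus a permuted draw passed the real 1393. It was not below 0.05 for the 8 genes of An. coluzzii. Why single draws reached 1492 calls there and 1621 in An. merus was not tested. The splits treat the libraries as exchangeable, and the permutation does so for the residuals of all 16 libraries of an interaction. In 7 of the 8 groups, replicates 1 and 2 against 3 and 4 differed most of the 3 ways to pair them. The shares therefore do not exclude chance where this assumption fails. With replicates 1 and 2 and replicates 3 and 4 as units, a comparison of 2 groups has 3 splits, too few for a share under 0.05.

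A single library stood apart from the other 3 of its group in 6 of 140 groups of values, where chance alone gives about 1 in 20. In An. merus at 18 h in SW, replicate 1 stood at 21 CPM for AGAP002849 (others 14.1 to 14.8) and 96.4 CPM for AGAP001722 (others 52.7 to 59.6). In An. merus at 18 h in FW, replicate 3 stood at 120 CPM for AGAP009591 (others 155 to 159), 50.6 CPM for AGAP005457 (others 505 to 520) and 20.4 CPM for AGAP005458 (others 244 to 263). In An. coluzzii at 18 h in FW, replicate 3 held 1 read of AGAP028216, or 0.072 CPM, and the others held 0.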

How the results depend on the processing

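Thinning, edgeR on the recovered reads, means of replicates 1 and 2 and of 3 and 4 as units, and the joint removal of An. coluzzii 18 h FW replicates 1 and 2 were chosen after seeing the data. No paired analysis was possible because library numbers run from 1 to 32 and pair no samples. The tests of the 26 gene lists and their variants were not run, since no identifier had a name. Of 1057 refits of the 48 results for named genes, 1003 kept direction and call, 54 (over 11 results) lost the call and 0 reversed.

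Calls under SW in An. coluzzii at 18 h (867) were 6 in a fit over the libraries of the comparison, 439 after thinning to 3769859 reads, 18 without FW replicates 1 and 2, and 135 to 1729 with 1 library left out. Those at 66 h (235) were 129 after thinning and 110 to 183 with 1 library left out. Thinning leaves fewer reads per gene; for the other settings the cause was not tested. With means of replicates as units, which leave 8 residual degrees of freedom, calls were 10 and 52 under SW in An. coluzzii at 18 h and 66 h, 4327 and 5026 in An. merus, 935 and 2102 for species and water (2201 and 3368 with libraries), and 393 and 3 for age and water in An. merus (1393 with libraries) and An. coluzzii. The 8 calls of age and water in An. coluzzii were 4 with a pseudocount of 0.25, 14 with a pseudocount of 4, 2 with a mean of at least 5 CPM, 3 in the fit over the libraries of the comparison, 5 with edgeR, 4 after thinning, 4 without FW replicates 1 and 2, and 5 to 27 with 1 library left out. Pearson's r between the ages of An. merus (0.752) was 0.705 with edgeR. The number of calls in each of the other comparisons stayed within 1.5 times under each alternative run, except those on means of replicates given above. With 1 library left out they were 4816 to 5300 for SW in An. merus at 18 h, 5572 to 5922 at 66 h, 1733 to 2293 and 3096 to 3332 for species and water, and 1028 to 1446 for age and water in An. merus. Over all comparisons, those in An. coluzzii included, 52 values of 2-fold or shared counts changed by more than 1.5 times.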

Other observations

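Chosen after the results were seen were the comparison of pairs of replicates within groups and the choice of which run to name. The SW responses of genes with neighbouring identifiers were weakly correlated. Across genes in identifier order, the mean SW response of An. merus had a correlation of 0.14 between next neighbours. That lay above the 0.0313 that was the highest of 1000 shuffles, and in An. coluzzii the correlation was 0.17. It was not computed for differences of age, species or replicates, so these values do not show that it is particular to SW. Among 1030 genes called and changed at least 2-fold in An. merus at both ages, 9 runs of 3 or more next neighbours moved in 1 direction, 6 up and 3 down, with 28 genes in all. Shuffled orders gave a median of 2 such runs and a maximum of 9, which equals the number found. The run of greatest change was AGAP004581 to AGAP004583, with a mean log2 fold change of 4.28, and the longest, AGAP011293 to AGAP011297, held 4 genes with a mean of 1.07. Neighbours may share regulation or reads between similar copies, and these were not told apart, because no sequence was used here.

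A hypothesis was that genes An. coluzzii moves under SW are already set in that direction in An. merus in FW. Of the genes called at 66 h, 129 of 235 (54.9%) had a log2 difference between the species in FW at 18 h, called or not, with the sign of the SW response, within the 45.1% to 57.4% (95% range) of 10000 random draws of genes matched on expression. The libraries of that age enter the call through the pooled spread but not the fold change. Of those called at 18 h, 487 of 867 (56.2%) had the same sign in FW at 66 h, where draws gave 50.5% to 57% around 53.7%, so the tests did not bear the hypothesis out and leave it open.

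A further hypothesis was that SW shifts larval development in An. coluzzii. The correlation across genes of its SW response with the age difference of An. merus in FW was 0.00642 ± 0.092 (jackknife SE) at 66 h, which argues against it at that age, and 0.217 ± 0.17 at 18 h, which leaves it open.

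The split of An. coluzzii at 18 h in FW prompted a look at the other 7 groups. In 6 of them the difference between replicates 1 and 2 and replicates 3 and 4 had the largest SD of the 3 ways to pair them (one-sided exact binomial test, p = 0.0069). The directions were not shared: correlations of these differences between groups ran from -0.352 to 0.416, and 14 of 28 were positive.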
